A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

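The deposited files held, per the file headers, background-corrected intensity values and flags for each spot from Feature Extraction 10.7.3.1, with 2 spots for each of 6256 gene probes. The processed intensity was used, as log2, and the 2 spots of a probe were averaged after 50 outlier spots over all arrays were left out. No gene spot was saturated. The deposited value table held, per the labels, log2 signals of the authors. On each of its arrays at least 99.58% of the probes lay within 0.05 of the log2 processed intensity plus 1 constant, and the arrays had been brought to a different median at each time. For this reason the deposited log2 table was used only as an alternative, since it was not comparable between times. How the authors chose these constants is not given in the sources used here, nor is any filter of theirs.

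Arrays were scaled to their 75th percentile. A probe was kept when it was well above background on at least 2 arrays, which left 6184 and removed 72. A limma model with 1 mean per group was fitted with 8 residual and 3.26 prior degrees of freedom, and p-values were adjusted per comparison by Benjamini and Hochberg with a threshold of 0.05. Gene lists with at least 5 members were tested with camera at a preset correlation of 0.01, for 41 lists, and again with camera at an estimated correlation and with fry. The design, the groups, the comparisons, the gene lists, the 30 genes of interest and the first set of alternatives were chosen before the data were examined. Named genes were the 10 largest changes per direction among those that passed, or the 5 of smallest p per direction when few passed, beside 2 members per direction of the lists discussed. Counts adjusted over the list alone used Benjamini and Hochberg within that list, with no correction across lists or comparisons. They do not replace the adjustment over all genes. A list of transposon genes was dropped because it matched other open reading frames, and 4 list members were not on the arrays. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

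A table of locus tags and symbols was used for names and neighbours, to match list members and to mark identifiers absent from the annotation. It matched 5756 of the 6256 probe identifiers, and 500 were not matched. In a self-test on the 187 h comparison, genes were shifted by known amounts. Of 50 genes per size, 8 were recovered at 0.5 log2, 35 at 1, 45 at 2 and 49 at 3, with 9 false calls. The shifted list was called and no other list was. The simulated noise was drawn independently for each gene, so the self-test does not show how often camera calls lists of correlated genes. The alternatives were the median of each array, quantile normalization, spike-in scaling with 7 spike-in probes, normexp with quantile normalization, the deposited log2 table, other filters, a replicate block, a vessel block, another variance model, a constant added to dim signals, probes with 2 differing spots left out, the dark central area left out, single times and single arrays left out, and the compared times fitted alone. Normexp was run on the median spot signal because a column of mean signals was not found in the files used here. Choosing among several probes per gene was not run because each gene had 1 probe.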

Results

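The series held 16 one-colour arrays of the wine yeast Lalvin EC1118 fermenting a synthetic must at 22 °C. In the mixed fermentations Dekkera bruxellensis grew on the other side of a dialysis membrane, and in the control fermentations the other side was sterile. Cells were taken at 22 h (exponential growth), 92 h (early stationary phase), 144 h (late stationary phase) and 187 h (decline), with duplicate fermentations of each kind, so each of the 8 groups had n = 2 arrays. Values are log2 differences with standard errors, relative to the 75th percentile of each array, and p-values from limma were adjusted over 6184 genes. The labels do not say whether the same-numbered arrays of a kind came from 1 vessel sampled 4 times. If they did, the p-values of the average over times would be too small. The first principal component, with 73.9% of the variance, ordered the arrays by time. On both slides the mixed arrays lay in 1 row and the controls in the other, and each time had its own column. Effects of kind and of time therefore cannot be told apart from effects of place on the slide by the layout alone.

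Averaged over the 4 times, 530 genes differed between mixed and control fermentations (198 higher and 332 lower in mixed, 8 arrays against 8), and the clearest rise was in the seripauperin (PAU) genes, a cell wall family known for expression under anaerobic and low-sterol conditions. All 25 genes of the list, which also holds DAN2 and TIR2, rose, by 0.63 to 1.68, with a median of 1.12 (slide medians 0.80 and 1.45), and all 25 also passed when adjusted over the list alone. PAU5 (1.68 ± 0.29, adjusted p = 0.0154), PAU17 (1.64), PAU7, PAU23 (1.35), PAU2 (1.29), PAU16 (1.18) and PAU3 (1.16) stood among the 10 largest rises. The list was called by camera at its preset correlation (adjusted p = 1.46e-22) but not with an estimated correlation (adjusted p = 0.454 with an estimated correlation). The PAU genes are near-identical copies, so which of them rose is uncertain by probe. Genes of the anaerobic cell wall (DAN/TIR) list moved the same way, with 6 of 19 higher and 1 lower (8 and 1 adjusted over the list alone), a median of 0.39, and adjusted p = 2.41e-05, or adjusted p = 0.454 with an estimated correlation. Its members PAU23 and PAU24 (1.14 ± 0.25) are shared with the PAU list, and CWP2 fell (-0.43). Of 33 genes of ergosterol synthesis and sterol uptake 2 rose, the sterol importer AUS1 (1.01 ± 0.25) and the synthase ERG13 (0.60 ± 0.11), with 2 rises also adjusted over the list alone and a list median of 0.19 (adjusted p = 8.72e-08, or adjusted p = 0.454 with an estimated correlation). At 187 h that list was not called, with slide medians of 0.07 and 0.02.

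**Figure D1:**
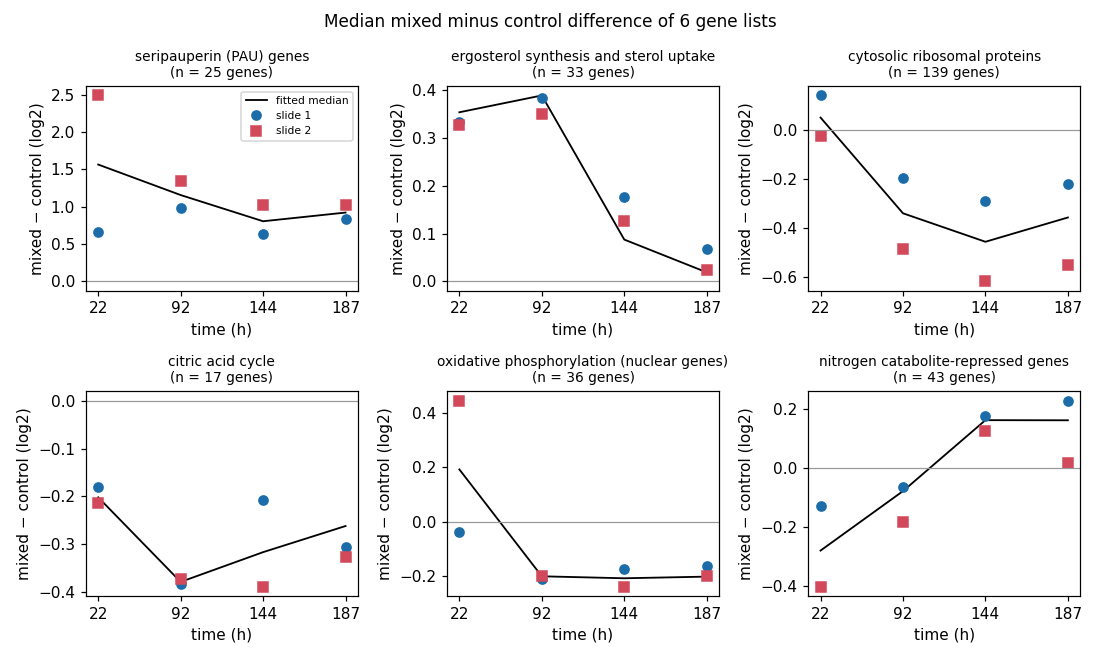
Median log2 difference of selected gene lists, mixed against control fermentations, at each of the 4 times, fitted and by slide. Seripauperin genes had the largest median of these lists at each time. In the average over the times, which is not drawn, it was 1.12.

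Genes of translation, the citric acid cycle and amino acid synthesis were lower in the mixed fermentations on average. Of 139 cytosolic ribosomal protein genes 54 fell and 0 rose (95 and 1 adjusted over the list alone), with a median of -0.27 and slide medians of -0.14 and -0.42 (adjusted p = 1.09e-22, or adjusted p = 0.546 with an estimated correlation). RPL3 fell by 0.45 (adjusted p = 0.0241). Of 17 citric acid cycle genes 9 fell (11 adjusted over the list alone), led by the aconitase ACO1 (-0.77) and the succinate dehydrogenase subunit SDH3 (-0.65 ± 0.08, adjusted p = 0.00682), with a list median of -0.23 (adjusted p = 6.55e-07, or adjusted p = 0.454 with an estimated correlation). The oxidative phosphorylation list was not called in the average (median -0.10, adjusted p = 0.108). Of 68 amino acid biosynthesis genes 14 fell and 0 rose (22 lower adjusted over the list alone), with a median of -0.21 (adjusted p = 8.28e-08, or adjusted p = 0.546 with an estimated correlation). The branched-chain pathway genes ILV3 (-0.62), LEU2 (-0.54 ± 0.07, adjusted p = 0.0067) and BAT2 (-0.55) were among the largest falls. The serine and threonine deaminase gene CHA1, which is induced by its substrates, fell most (-1.21 ± 0.19, adjusted p = 0.0130), and the allantoate permease gene DAL5 (-0.68), the putative vacuolar protease gene PFF1 (-0.65), MSA2 (-0.56) and YNR068C (-0.54) also fell. Of 67 mitochondrial ribosomal protein genes 8 fell, among them MRPL50 (-0.38) and MRPL38 (-0.30), and MRPS17 rose (0.32). That list's median was -0.14 (adjusted p = 0.000331, or adjusted p = 0.612 with an estimated correlation). Adjusted over the list alone, 12 fell and 3 rose. With fry, adjusted p was 0.0028 for the citric acid cycle, 0.0313 for the ribosomal protein and PAU lists and 0.0344 for the amino acid biosynthesis and DAN/TIR lists.

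Lists of sporulation, stress, thiamine, transport, iron and cell cycle genes also shifted in the average. Of 46 sporulation and meiosis genes 6 rose, with SPS100 (1.07) and IME2 (0.84), and SPS4 fell (-0.54). Their median was 0.16, or 0.05 with normexp (adjusted p = 2.41e-05, or adjusted p = 0.454 with an estimated correlation), and 7 rose and 1 fell adjusted over the list alone. Of 47 general stress response genes 4 rose and 2 fell (7 and 2 adjusted over the list alone), with SPG4 (0.77) and PHM7 (0.51) higher and OM14 (-0.46) and HXK1 (-0.36) lower. The stress list's median was 0.15 (adjusted p = 0.00026, or adjusted p = 0.546 with an estimated correlation). The small heat shock gene HSP12 rose (1.21 ± 0.24, adjusted p = 0.0194), as did APJ1 (0.52), and the heat shock and chaperone list of 33 had a median of 0.11 and the same 2 rises adjusted over the list alone (adjusted p = 0.0207, or adjusted p = 0.612 with an estimated correlation). Of 22 thiamine genes THI22 (1.02) and PET18 (0.37) rose, with 5 higher and 1 lower adjusted over the list alone and a median of 0.24 (adjusted p = 0.000117, or adjusted p = 0.546 with an estimated correlation). Of 24 amino acid permease genes 3 rose, among them the methionine permease MUP1 (0.79 ± 0.09) and the 4-aminobutyrate permease UGA4 (0.55). The permease list had a median of 0.03 and 4 rises adjusted over the list alone (adjusted p = 0.0418, or adjusted p = 0.546 with an estimated correlation). Of 30 iron regulon genes FRE4 (0.66) and COT1 (0.35) rose and FIT1 (-0.43) and VHT1 (-0.39) fell, 2 each way also adjusted over the list alone, with a median of 0.14 (adjusted p = 0.0169, or adjusted p = 0.546 with an estimated correlation). Of 51 cell cycle and DNA replication genes 4 fell, with RNR1 (-0.47) and MCM7 (-0.32) and 4 also adjusted over the list alone, and the median of -0.11 (adjusted p = 0.0298, or adjusted p = 0.612 with an estimated correlation) became 0.01 with spike-in scaling.

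Among 30 genes of interest, the flocculin FLO11 fell on average (-1.04 ± 0.22, adjusted p = 0.0239) and the weak-acid exporter PDR12 fell (-0.30, adjusted p = 0.0409), beside HSP12 and RPL3. The other 26 did not pass and lay between SUC2 (-0.35 ± 0.11, adjusted p = 0.0668) and FIT2 (0.71 ± 0.28, adjusted p = 0.126). FLO11, which encodes a cell surface adhesin, had a lower mean at each time, by 0.49, 1.06, 1.16 and 1.46 at 22 h, 92 h, 144 h and 187 h. In limma it passed at no single time (adjusted p = 0.882, 0.815, 0.480 and 0.0666). At 22 h the standard deviation of its control arrays was 1.28, larger than the difference. Several open reading frames without a known product rose, among them YCL023C (1.39 ± 0.20, adjusted p = 0.00978), YNL120C (1.47) and YPL073C (at least 1.65-fold). For a gene with all arrays of 1 side of a comparison under background the fold is a lower bound, taken against the lowest signal well above background. The average count depended on single times and arrays. With spike-in scaling it was 135, with 131 higher and 4 lower, so the balance turned. It was 216 with a vessel block and 0 with the mean of each vessel, a fit with fewer residual degrees of freedom. It was also 0 by limma when the 187 h difference was left out of the average, with all arrays kept in the fit. In the full model 1727 genes had an unadjusted p under 0.05. The count also varied when single arrays were left out. With the median of each array as scale 55.5% of the called genes were higher, against 37.4% with the 75th percentile. Of the average calls also called in the steps to 92 h, 144 h and 187 h in turn, 116, 64 and 47 were higher in both. Lower in both were 206, 127 and 92, and opposite 73, 10 and 5. From 92 h mixed arrays also lay ahead of the same slide's controls on the first principal component. A lead in time of the mixed fermentations therefore stays open for these calls.

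**Figure D2:**
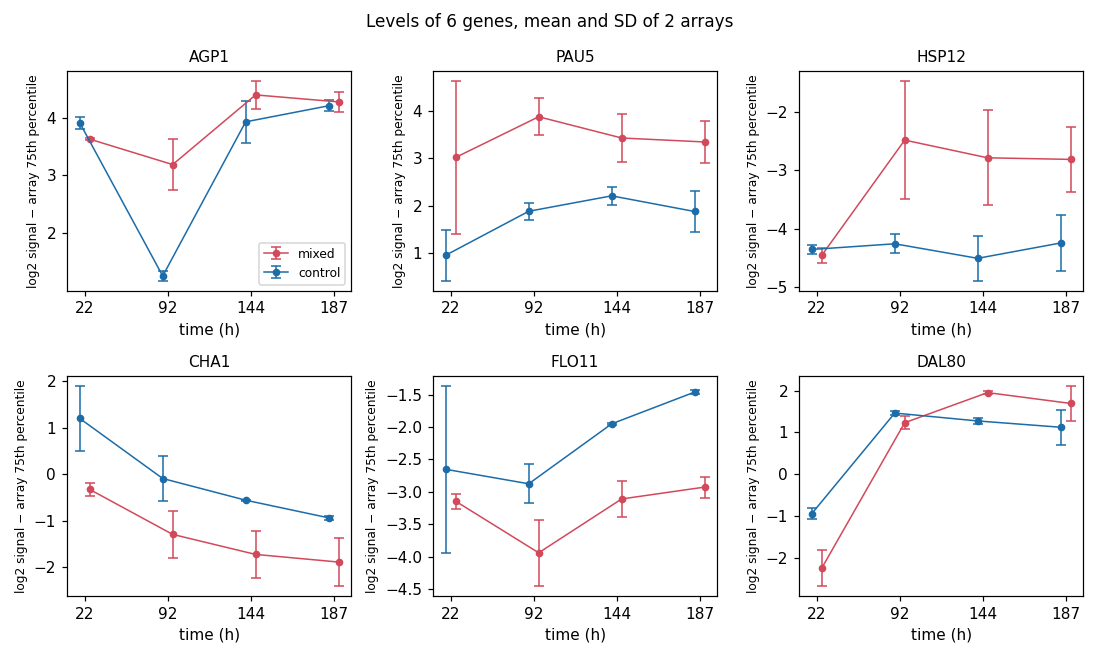
Log2 signal of selected genes relative to the 75th percentile, by time in mixed and control fermentations, with 2 arrays per group. AGP1 stood 1.93 higher in mixed fermentations at 92 h, when its control level had fallen to 1.26.

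At 22 h, in exponential growth, the PAU genes had the largest list shift, with a median of 1.57 (adjusted p = 1.08e-30, or adjusted p = 0.605 with an estimated correlation). It was 0.67 on the first slide and 2.49 on the second, with 1 array per kind on each, and PAU3 (1.60) and PAU21 (1.52 ± 0.39) were among its members, with 24 of 25 higher adjusted over the list alone. Ergosterol and sterol uptake genes had a median of 0.35 (0.23 with quantile normalization), with HMG1 (0.88) and ERG13 (0.70) (adjusted p = 5.21e-08, or adjusted p = 0.629 with an estimated correlation). Thiamine genes had a median of 0.41, with THI12 (2.65) and THI22 (1.80) and 5 higher adjusted over the list alone (adjusted p = 6.39e-11, or adjusted p = 0.629 with an estimated correlation), but the slides gave -0.02 and 1.05. General stress response genes had a median of 0.24, led by the catalase gene CTT1 (1.26 ± 0.23) and SOL4 (0.91), with 2 higher adjusted over the list alone (adjusted p = 2.66e-05, or adjusted p = 0.629 with an estimated correlation), with slide medians of -0.12 and 0.39. Genes under nitrogen catabolite repression had a median of -0.28, with the GATA repressor DAL80 (-1.31 ± 0.25) and BAT2 (-0.61), and 1 lower adjusted over the list alone (adjusted p = 2.11e-06, or adjusted p = 0.605 with an estimated correlation). Lists that were lower later were called higher at 22 h, but with opposite signs on the slides. They were ribosomal protein genes (0.05, turned to -0.03 with quantile normalization, slides 0.14 and -0.02, adjusted p = 0.00603, or adjusted p = 0.836 with an estimated correlation), oxidative phosphorylation genes (0.19, slides -0.04 and 0.44, adjusted p = 3.15e-05, or adjusted p = 0.640 with an estimated correlation) and ribosome biogenesis genes (0.20, slides -0.41 and 0.83, adjusted p = 1.34e-06, or adjusted p = 0.738 with an estimated correlation). Without the second control array of 22 h ribosome biogenesis was called lower, and the oxidative phosphorylation and general stress calls ended. Without the second mixed array the ribosome biogenesis call ended, and without the first control array the ribosomal protein call, as with quantile normalization, normexp and spike-in scaling. No single gene passed in limma, 391 having an unadjusted p under 0.05. CTT1 (adjusted p = 0.498), YJL127W-A (1.09), YHL005C (under background in both groups) and OSW1 (at least 1.47-fold) were the other genes of smallest p on the higher side, and CHA1 (-1.53 ± 0.38), YJR149W (-0.94), YBR300C (-0.79) and RNR1 (-0.58) on the lower side. Spike-in scaling put the all-gene median at 0.51, against -0.02, and turned 7 of the 20 list medians called at 22 h, those of amino acid biosynthesis, biotin and related vitamins, cell cycle, citric acid cycle, nitrogen catabolite repression, purines and sulfur.

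At 92 h the amino acid permease gene AGP1 was the only gene that passed (1.93 ± 0.22, adjusted p = 0.0143), with 348 genes at an unadjusted p under 0.05 in limma. Its level in the controls went from 3.91 at 22 h to 1.26 at 92 h and 3.93 at 144 h. In the mixed fermentations it was 3.63, 3.19 and 4.39, so the difference lay in a fall of the controls rather than a rise in mixed fermentations. AGP1 did not pass when only the 92 h arrays were fitted, nor when either control array or the second mixed array of 92 h was left out. The open reading frame YCL023C, close to AGP1 on chromosome III, was also high (2.13 ± 0.39, adjusted p = 0.345), as were PAU17 (2.39), YML083C (0.88) and MUP1 (0.88). FUM1 (-0.75), YHM2 (-0.72), YLR255C (-0.78), BAT2 (-0.70) and PDR12 (-0.66) had the smallest p among the lower genes without passing. Ribosomal protein genes had a median of -0.34 (slides -0.20 and -0.48), with RPS1B (-0.52) and RPL10 (-0.52) (adjusted p = 1.2e-39, or adjusted p = 0.605 with an estimated correlation). Citric acid cycle genes had a median of -0.38 (slides -0.38 and -0.37), with FUM1 and SDH3 (-0.61) and 3 lower adjusted over the list alone (adjusted p = 4.53e-12, or adjusted p = 0.605 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.20, with ATP5 (-0.45) and COR1 (-0.36) (adjusted p = 9.03e-06, or adjusted p = 0.629 with an estimated correlation). PAU genes had a median of 1.16, with PAU17 and PAU23 (1.79) and 16 higher adjusted over the list alone (adjusted p = 4.37e-25, or adjusted p = 0.605 with an estimated correlation). All 33 ergosterol and sterol uptake genes had positive differences, with a median of 0.39 and with ERG13 (0.71) and SUT2 (0.60) (adjusted p = 6.43e-15, or adjusted p = 0.605 with an estimated correlation). Sporulation genes had a median of 0.37 (0.12 with normexp), with SPR28 (0.78) and DMC1 (0.72) and 3 higher adjusted over the list alone (adjusted p = 1.64e-10, or adjusted p = 0.605 with an estimated correlation).

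At 144 h no single gene passed in limma, with 567 at an unadjusted p under 0.05. Counts adjusted over a list alone are therefore not calls of single genes here. Ribosomal protein genes had a median of -0.46 (slides -0.29 and -0.62), with RPL13A (-0.69) and RPS28B (-0.68) and 74 lower adjusted over the list alone (adjusted p = 1.2e-40, or adjusted p = 0.605 with an estimated correlation). PAU genes had a median of 0.81 (slides 0.64 and 1.02), with PAU17 (1.27) and TIR2 (0.81) (adjusted p = 1.18e-11, or adjusted p = 0.629 with an estimated correlation). Citric acid cycle genes had a median of -0.32, with SDH3 (-0.68) and FUM1 (-0.52) and 2 lower adjusted over the list alone (adjusted p = 0.00186, or adjusted p = 0.629 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.21, with ATP16 (-0.49) and ATP4 (-0.47) (adjusted p = 0.00247, or adjusted p = 0.686 with an estimated correlation). Amino acid permease genes had a median of 0.17, with MUP1 (1.07) and UGA4 (0.88) and 2 higher adjusted over the list alone (adjusted p = 0.000272, or adjusted p = 0.605 with an estimated correlation). Genes under nitrogen catabolite repression, lower at 22 h, had a median of 0.16 (slides 0.18 and 0.13), with UGA4 and the ammonium permease gene MEP2 (0.53) and 1 higher adjusted over the list alone (adjusted p = 0.0088, or adjusted p = 0.659 with an estimated correlation). Sporulation genes had a median of 0.11, with IME2 (1.46 ± 0.25, adjusted p = 0.218) and SPR28 (0.87) and 2 higher adjusted over the list alone (adjusted p = 0.00896, or adjusted p = 0.659 with an estimated correlation). Without the first mixed array of 144 h the permease, nitrogen and sporulation calls ended, and without the second control array the sporulation call, whose median was 0.19 with quantile normalization. MTR4 (1.30) was also among the higher genes of smallest p, and PFF1 (-1.34), the ribosome-bound chaperone gene SSB2 (-0.91), YHM2 (-0.63) and PET191 (-0.48) were among the lower.

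At 187 h, in decline, 449 genes differed (174 higher and 275 lower in mixed), and ribosomal protein and citric acid cycle genes were among those that fell. The maltase gene MAL32 fell by 1.75 ± 0.41 and the flavohemoglobin gene YHB1 by 1.35 ± 0.27 (adjusted p between 0.0264 and 0.0374 for the 10 largest falls). The ribosome-associated chaperones SSB2 (-1.23) and SSB1 (-1.22), RPL22B (-1.20), REE1 (-1.19), USA1 (-1.18), OM14 (-1.18), YBR174C (-1.29) and YNR061C (-1.18) also fell. SSB1 and SSB2 are close copies, so which of them fell is uncertain by probe. Of 139 ribosomal protein genes 24 fell, with RPL22B and RPL30 (-0.93), and 47 fell adjusted over the list alone, with a list median of -0.36 (adjusted p = 5.56e-11, or adjusted p = 0.669 with an estimated correlation). Of 67 mitochondrial ribosomal protein genes 11 fell, with MRPL50 (-0.91) and MRP4 (-0.69), and 3 rose, with MRP8 (0.79) and MRPL16 (0.65). With 27 falls and 4 rises adjusted over the list alone, the list median was -0.28 (adjusted p = 0.000181, or adjusted p = 0.669 with an estimated correlation). Of 17 citric acid cycle genes 3 fell, with SDH3 (-0.99) and SDH4 (-0.71) and 5 falls adjusted over the list alone. The median was -0.26 (adjusted p = 0.0025, or adjusted p = 0.629 with an estimated correlation). Of 68 amino acid biosynthesis genes 5 fell, with LEU2 (-0.95) and ARO2 (-0.87) and 8 falls adjusted over the list alone. The median was -0.27 (adjusted p = 0.0025, or adjusted p = 0.738 with an estimated correlation). Ribosome biogenesis genes had 4 falls, with NOP56 (-0.90) and RRP5 (-0.76) and 1 fall adjusted over the list alone. The median was -0.25 (adjusted p = 0.0249, or adjusted p = 0.841 with an estimated correlation).

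The genes called higher at 187 h included many open reading frames without a known product and dim signals. YER119C-A (at least 3.77-fold), YPL073C (at least 3.60-fold), YJL015C (at least 3.32-fold), YEL014C (at least 2.96-fold), YNL120C (2.31 ± 0.47), YGL149W (2.12), YNL028W (2.11), YJL032W (1.95), YMR245W (1.78) and BIL2 (1.78 ± 0.23) rose most. Among characterized genes the protein kinase gene KCC4 rose (1.60 ± 0.27, adjusted p = 0.0264). Sporulation genes had 3 rises and 1 fall, with IME2 (1.41), SPR28 (1.01) and OSW1 (-1.12) and 4 rises and 1 fall adjusted over the list alone. The median was 0.13 (adjusted p = 0.0193, or adjusted p = 0.669 with an estimated correlation). Sulfur and methionine genes had 5 rises, with SAM1 (0.96) and CYS3 (0.92) and 9 rises and 1 fall adjusted over the list alone and a median of 0.03, which turned negative with spike-in scaling (adjusted p = 0.0161, or adjusted p = 0.738 with an estimated correlation). Genes under nitrogen catabolite repression had 3 rises, with UGA4 (1.14) and GZF3 (0.85), and 2 falls, PUT2 (-0.84) and UGA1 (-0.48), the same numbers adjusted over the list alone, with a median of 0.16 (adjusted p = 0.0481, or adjusted p = 0.715 with an estimated correlation). RPT2 (0.68) and RPN1 (0.61) rose in the proteasome list, with 4 rises and 1 fall adjusted over the list alone. The median was 0.12 (adjusted p = 0.0284, or adjusted p = 0.742 with an estimated correlation). APJ1 (0.98) rose in the heat shock list, with 0 passing adjusted over the list alone in limma and a median of 0.19 (adjusted p = 0.0133, or adjusted p = 0.738 with an estimated correlation). In the DAN/TIR list the median was 0.49, and PLB2 rose (1.54), as it did adjusted over the list alone (adjusted p = 0.00544, or adjusted p = 0.629 with an estimated correlation). PAU genes had a median of 0.92 with no single member passing (adjusted p = 4.19e-07, or adjusted p = 0.669 with an estimated correlation).

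The count at 187 h and its balance depended on single arrays and on scaling. On the first mixed array of 187 h spots of the central area lay high, by a median of 0.18 log2. The first control array of 187 h had a dark central area. With the spots of that area left out on all arrays 269 genes were called, without that array 2, without the second mixed array 88 (84 higher and 4 lower), with spike-in scaling 42 (36 higher and 6 lower), and with the 187 h arrays fitted alone 0. YJL032W, with a spot in that area, had adjusted p = 0.071 without it. A fit of the arrays of a single time had fewer residual degrees of freedom and called 0 genes at each time. Its 0 at 187 h therefore does not show a dependence on arrays or scaling. With the median of each array as scale 60.9% of the called genes were higher, against 38.8% with the 75th percentile. Of the 187 h calls also called from 144 h to 187 h, 50 were higher in both, 73 lower in both and 5 opposite. A lead in time stays open here too. The call of the nitrogen list ended with the median of each array, quantile normalization, spike-in scaling, normexp and the deposited table, and without any 1 of 10 arrays. These were both mixed arrays of 22 h and of 92 h, both control arrays of 22 h, the first control arrays of 92 h and 187 h, the second control array of 144 h and the first mixed array of 187 h. The proteasome and heat shock calls ended with quantile normalization, spike-in scaling and normexp, and the sporulation and ribosome biogenesis calls with quantile normalization and normexp, where the medians were 0.02 and 0.05 for sporulation. Without the second mixed array of 187 h the proteasome, heat shock, DAN/TIR and ribosome biogenesis calls ended, without the first control array the heat shock and ribosome biogenesis calls, without the second control array the proteasome, sporulation and sulfur calls, and without the first mixed array the sporulation call.

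No gene passed the limma F test for a mixed minus control difference that varied with time, with 441 at an unadjusted p under 0.05. AGP1, whose difference was -0.28, 1.93, 0.47 and 0.07 at the 4 times, had the smallest p, with URA10, OSW1, UGA4, RTS3, DAL80, KCC4, YHR180W and SOL4 at the same adjusted p of 0.366. DAL80 went from -1.31 at 22 h to -0.23, 0.68 and 0.57, and KCC4 from -0.44 to -0.20, 1.07 and 1.60. CHA1 had a lower mean at each time (-1.53, -1.20, -1.17 and -0.95), and HSP12 a higher mean from 92 h (-0.10, 1.77, 1.72 and 1.43). In limma neither passed at any single time (lowest adjusted p = 0.128 and 0.0796, both at 187 h).

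From 22 h to 92 h, as cells left exponential growth, 4042 genes changed on average over both kinds of fermentation (2236 higher and 1806 lower, 855 and 588 of them at least 2-fold). The high-affinity hexose transporters HXT6 (6.49) and HXT7 (6.29) rose with the sporulation-specific SLZ1 (6.53 ± 0.18), the stationary phase genes SPG1 (6.12) and SPG4 (5.88), and the stress genes HSP26 (5.94) and DDR2 (5.93). SHH3 (5.92), the glycogen regulator GAC1 (5.88) and STE3 (at least 40.1-fold) completed the 10 largest rises. HXT6 and HXT7 are near-identical, so which of them rose is uncertain by probe. The acid phosphatase PHO3 (-3.56 ± 0.15), YJL213W (-3.50), the Ehrlich pathway genes ARO10 (-3.20) and ARO9 (-2.93), YGR266W (-3.15), the permease BAP3 (-3.14), HMG1 (-3.14), AIM20 (-3.12), MET3 (-3.05) and PIR1 (-2.96) fell most. Spike-in scaling put the all-gene median at -1.09, against 0.07, and 7.10% of called genes were then higher, against 55.3% with the 75th percentile and 46.9% with quantile normalization, so these changes are relative to the bulk of genes.

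**Figure D3:**
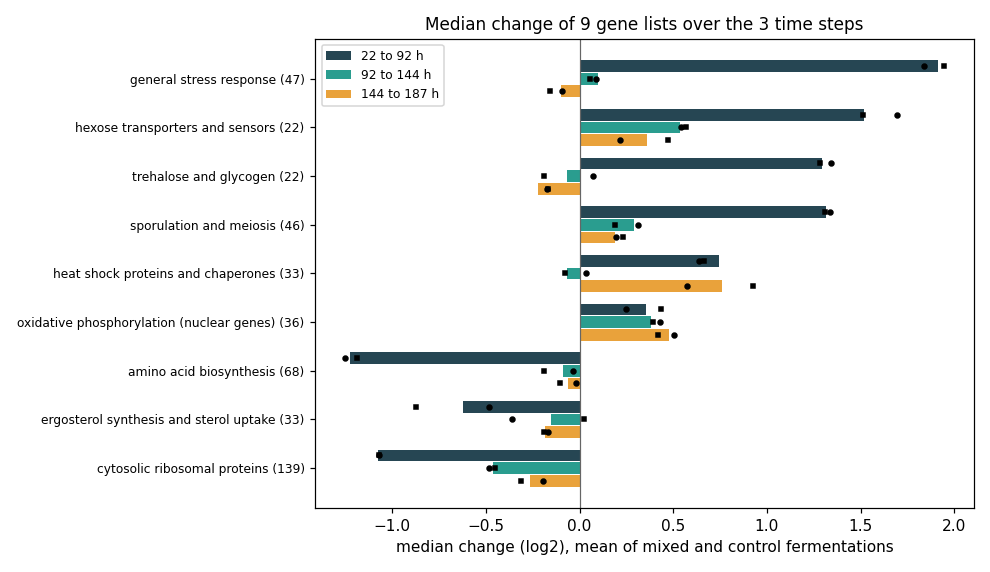
Median log2 change of gene lists over the 3 time steps, averaged over mixed and control fermentations. General stress response genes rose by a median of 1.91 from 22 h to 92 h.

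Stress, storage and alternative carbon genes rose from 22 h to 92 h, and the counts of rises and falls adjusted over the list alone were the same except for 20 rises of hexose transporters. Of 47 general stress response genes 45 rose and 0 fell. The median was 1.91 (adjusted p = 2.77e-13, or adjusted p = 0.459 with an estimated correlation). Of 22 trehalose and glycogen genes 20 rose, with GAC1 and GIP2 (3.87), and PGM1 (-1.83) and TPS3 (-0.41) fell. The median was 1.29 (adjusted p = 9.03e-06, or adjusted p = 0.459 with an estimated correlation). Of 22 hexose transporters and sensors 19 rose, and the low-affinity HXT1 fell (-2.22). The median was 1.52 (adjusted p = 0.0002, or adjusted p = 0.459 with an estimated correlation). Of 23 glyoxylate cycle and gluconeogenesis genes 16 rose, with ADH2 (3.67) and ACS1 (2.79), and 4 fell, with CIT2 (-1.96) and YAT2 (-1.33). The median was 1.30 (adjusted p = 0.00102, or adjusted p = 0.464 with an estimated correlation). Of 46 sporulation genes 39 rose, with REC8 (5.17) and OSW1 (4.74, a size that is uncertain because both control arrays of 22 h were under background), and SPO21 fell (-0.47). The median was 1.31 (adjusted p = 1.25e-07, or adjusted p = 0.459 with an estimated correlation). Of 46 autophagy genes 30 rose, with ATG39 (3.71) and ATG45 (2.51), and 4 fell, with ATG41 (-1.98) and CPS1 (-0.87). The median was 0.71 (adjusted p = 0.000537, or adjusted p = 0.459 with an estimated correlation). Of 33 heat shock and chaperone genes 21 rose, with HSP26 and HSP30 (4.44), and 2 fell, SSA2 (-2.27) and SSE1 (-0.52). The median was 0.74 (adjusted p = 0.00874, or adjusted p = 0.793 with an estimated correlation). Of 43 beta-oxidation and peroxisome genes 23 rose, with SPS19 (3.88) and POT1 (3.60), and 7 fell, with ANT1 (-1.85) and PEX21 (-1.40). The median was 0.38 (adjusted p = 0.0441, or adjusted p = 0.585 with an estimated correlation). The beta-oxidation call ended with the deposited table and without the second mixed array of 22 h or of 92 h. The sporulation median was 0.57 with quantile normalization and 0.28 with normexp, and with normexp the hexose transporter median was 0.48 and the glyoxylate cycle median 0.81. With spike-in scaling the medians of autophagy, beta-oxidation, heat shock, haploid-specific and mitochondrially encoded genes turned negative.

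Growth, amino acid, sulfur and sterol genes fell over the same step, and the counts adjusted over the list alone were the same except for 55 falls in amino acid biosynthesis and 24 in sulfur and methionine. Of 139 ribosomal protein genes 133 fell, with RPL9A (-2.09) and RPS9B (-2.01). The median was -1.07 (adjusted p = 4.52e-28, or adjusted p = 0.459 with an estimated correlation). Of 68 amino acid biosynthesis genes 54 fell, with SER33 (-2.46) and LEU9 (-2.36), and 6 rose, with CPA1 (1.34) and SER3 (1.29). The median was -1.22 (adjusted p = 1.44e-12, or adjusted p = 0.459 with an estimated correlation). Of 33 sulfur and methionine genes 23 fell, with MET3 and MUP1 (-2.68), and 2 rose, MET31 (1.72) and MET4 (0.57). The median was -1.08 (adjusted p = 3.73e-05, or adjusted p = 0.594 with an estimated correlation). Of 33 ergosterol and sterol uptake genes 24 fell, with HMG1 and ERG13 (-1.91), and 3 rose, with PDR11 (1.76) and UPC2 (1.61). The median was -0.62 (adjusted p = 0.000261, or adjusted p = 0.587 with an estimated correlation). Of 24 aroma compound synthesis genes 14 fell, with ARO10 and ARO9, and 2 rose, PDC6 (2.25) and IAH1 (0.48). The median was -0.60 (adjusted p = 0.00576, or adjusted p = 0.459 with an estimated correlation). Purine and one-carbon genes had a median of -0.99 (adjusted p = 0.587 with an estimated correlation), ribosome biogenesis genes -0.75 (adjusted p = 0.826 with an estimated correlation), biotin and related vitamin genes -0.83 (adjusted p = 0.459 with an estimated correlation), iron regulon genes -0.58 (adjusted p = 0.587 with an estimated correlation) and cell cycle genes -0.27 (adjusted p = 0.793 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of 0.36 without being called (adjusted p = 0.271).

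From 92 h to 144 h 951 genes changed on average (392 higher and 559 lower, 86 and 14 of them at least 2-fold). YNR071C (3.35 ± 0.23), the transporters HXT16 (3.07) and HXT15 (2.54), the mannitol dehydrogenases MAN2 (2.60) and DSF1 (2.39), YJL032W (2.75), CSM4 (at least 4.15-fold), YHR033W (2.33), RGI2 (2.27) and IRC8 (2.22) rose most. HXT15 with HXT16, and MAN2 with DSF1, are near-identical pairs, so which member rose is uncertain by probe. YPR014C (-1.85), YGR035C (-1.82), ECM13 (-1.49), the glyceraldehyde-3-phosphate dehydrogenase TDH3 (-1.43 ± 0.15), FMP48 (-1.37), YLR235C (-1.36), AAH1 (-1.32), BSC1 (-1.31), PRM9 (-1.29) and MST27 (at least 1.73-fold lower) fell most. Of 36 oxidative phosphorylation genes 13 rose, with NDE1 (2.19) and CYC1 (1.84) and 19 rises adjusted over the list alone. The median was 0.38 (adjusted p = 3.26e-11, or adjusted p = 0.459 with an estimated correlation). Glyoxylate cycle genes had 12 rises, with ADY2 (1.07) and CRC1 (1.01), and MDH2 fell (-0.60), with 13 rises and 1 fall adjusted over the list alone. The median was 0.41 (adjusted p = 1.97e-06, or adjusted p = 0.459 with an estimated correlation). Hexose transporters had 7 rises, and STD1 fell (-0.53), with 10 rises and 3 falls adjusted over the list alone. The median was 0.53 (adjusted p = 0.000473, or adjusted p = 0.459 with an estimated correlation). This call ended when only probes well above background on all arrays were kept. Sporulation genes had 9 rises, with OSW1 (1.52) and SMK1 (1.28) and 9 rises also adjusted over the list alone. The median was 0.29 (adjusted p = 9.2e-05, or adjusted p = 0.459 with an estimated correlation). Of 8 flocculin genes FLO5 (0.80) and FLO1 (0.62) rose, with 3 rises adjusted over the list alone. The median was 0.58 (adjusted p = 0.0109, or adjusted p = 0.585 with an estimated correlation). Mitochondrial ribosomal protein genes had 4 rises, with MRPS17 (0.91) and RSM7 (0.63) and 1 rise adjusted over the list alone. The median was 0.10 (adjusted p = 0.00117, or adjusted p = 0.768 with an estimated correlation). Ribosomal protein genes had 86 falls, with RPL8A (-1.17) and RPS9B (-0.93) and a median of -0.46, and 119 fell adjusted over the list alone (adjusted p = 1.75e-26, or adjusted p = 0.459 with an estimated correlation). Ribosome biogenesis genes had 6 falls, with RPA49 (-0.80) and NOP58 (-0.80) and 0 falls adjusted over the list alone in limma and a median of -0.21 (adjusted p = 0.00942, or adjusted p = 0.901 with an estimated correlation). The ribosome biogenesis call ended with the deposited table and without the first mixed array of 92 h. Of 29 biotin and related vitamin genes 8 fell, with BIO4 (-0.68) and BIO5 (-0.65), and FMS1 rose (0.71), with 9 falls and 1 rise adjusted over the list alone. The median was -0.20 (adjusted p = 0.00598, or adjusted p = 0.459 with an estimated correlation). Without the second control array of 92 h 251 genes were called, without the first control array of 144 h 286, without the second mixed array of 92 h 415 and without the first mixed array of 144 h 626. Spike-in scaling put the all-gene median at -0.35, against -0.06, and turned the medians of sporulation and mitochondrial ribosomal protein genes. With normexp the sporulation median was 0.07 and the hexose transporter median 0.33. With the median of each array as scale 56.9% of called genes were higher, against 41.2%.

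From 144 h to 187 h 700 genes changed on average (359 higher and 341 lower, 69 and 2 of them at least 2-fold), and heat shock genes rose. BTN2 (2.46 ± 0.41), FES1 (2.05), CPR6 (1.59) and ZPR1 (1.51), which encode chaperones or their partners, rose with MRT4 (2.08), YLR217W (at least 3.30-fold), YER053C-A (1.99), ARG3 (1.81), SPO75 (1.70) and PXP3 (1.70). YLR217W overlaps CPR6, so its rise is uncertain by probe. Of 33 heat shock and chaperone genes 20 rose, and HSP150 fell (-0.49), with 24 rises and 3 falls adjusted over the list alone. The median was 0.76 (adjusted p = 3.55e-12, or adjusted p = 0.459 with an estimated correlation). Of 36 oxidative phosphorylation genes 17 rose, with NDE1 (1.14) and COX4 (1.10) and 21 rises and 1 fall adjusted over the list alone. The median was 0.48 (adjusted p = 1.17e-11, or adjusted p = 0.459 with an estimated correlation). Of 13 mitochondrially encoded genes OLI1 rose (0.59), the 1 rise also adjusted over the list alone, with a median of 0.42 (adjusted p = 0.000749, or adjusted p = 0.459 with an estimated correlation). Sporulation genes had 10 rises, with GMC2 (1.44) and MEI4 (1.41) and 11 rises adjusted over the list alone. The median was 0.19 (adjusted p = 6.1e-05, or adjusted p = 0.459 with an estimated correlation). Hexose transporters had 5 rises, with HXT15 (1.92) and HXT16 (1.53) and 7 rises adjusted over the list alone. The median was 0.36 (adjusted p = 0.0144, or adjusted p = 0.594 with an estimated correlation). This call, too, ended when only probes well above background on all arrays were kept. STP22 (-1.05), TDH3 (-1.03), TIR4 (-0.90), AIM6 (-0.80), LAM5 (-0.80), MST28 (-0.79), RPL8A (-0.78), RPL8B (-0.77), RPS4A (-0.74) and RPS4B (-0.73) fell most, the last 4 being 2 pairs of close copies. Ribosomal protein genes had 22 falls, and 31 falls and 1 rise adjusted over the list alone. The median was -0.26 (adjusted p = 4.99e-09, or adjusted p = 0.768 with an estimated correlation). Of 24 glycolysis and ethanol formation genes 3 fell, with TDH3 and HXK1 (-0.45) and 5 falls adjusted over the list alone. The median was -0.25 (adjusted p = 0.00594, or adjusted p = 0.459 with an estimated correlation). Of 29 biotin and related vitamin genes 5 fell, with BIO4 (-0.62) and BIO2 (-0.51), and FMS1 rose (0.58), with 10 falls and 1 rise adjusted over the list alone. The median was -0.27 (adjusted p = 0.00198, or adjusted p = 0.459 with an estimated correlation). Without the second control array of 144 h 85 genes were called, 72 of them higher, and with only the compared times fitted 88, 75 of them higher. Without the first and second mixed arrays of 144 h 238 and 334 were called, and without the first control and second mixed arrays of 187 h 251 and 427. Spike-in scaling put the all-gene median at -0.32, against -0.06, and turned the median of sporulation genes, which was 0.07 with normexp, and with the median of each array as scale 79.5% of called genes were higher, against 51.3%. By kind of fermentation, 3264, 194 and 112 genes changed over the 3 steps in mixed and 3158, 70 and 1 in control fermentations.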

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

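The tests of the place along the first principal component, of the PAU level from 92 h, of oxidative phosphorylation beside the ribosomal protein genes and of the dark area among all genes called at 187 h were chosen only after the results were seen.

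Several gene lists shifted in opposite directions at 22 h and at a later time on both slides. The mixed minus control difference of genes under nitrogen catabolite repression was higher than at 22 h by 0.42 at 144 h (adjusted p = 5.67e-08, or adjusted p = 0.862 with an estimated correlation) and by 0.40 at 187 h (adjusted p = 1.74e-05, or adjusted p = 0.862 with an estimated correlation). Amino acid permeases were higher by 0.13 at 92 h (adjusted p = 0.0265, or adjusted p = 0.879 with an estimated correlation) and by 0.25 at 144 h (adjusted p = 0.00113, or adjusted p = 0.862 with an estimated correlation). Glycolysis and ethanol formation genes were lower, at -0.18, at 144 h (adjusted p = 0.0438, or adjusted p = 0.879 with an estimated correlation), and so were oxidative stress and redox genes, at -0.28 (adjusted p = 0.0399, or adjusted p = 0.879 with an estimated correlation). The opposite signs depended on scaling. The permease median at 22 h was -0.0014 and became 0.04 with the median of each array, the glycolysis median at 22 h became -0.05 with quantile normalization, and the redox median at 144 h became 0.03 with the median of each array. With spike-in scaling the nitrogen list had 0.26 at 22 h and 0.25 at 144 h.

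For 7 of the 30 genes of interest both mixed arrays lay above both control arrays at 1 time and below both at another, where 6.99 genes are expected by chance over the 4 times, so the number gives no sign of real reversals. The limma F test gave these genes adjusted p between 0.366 and 0.900 for a difference varying with time, and none passed. MEP2 had -0.57 at 22 h and 0.53 at 144 h, and its regulator DAL80 had -1.31 at 22 h and 0.68 at 144 h. The stress genes HSP30 (0.71 at 22 h and -1.43 at 187 h) and CTT1 (1.26 at 22 h and -0.45 at 187 h) were higher early and lower late. ATF1 had -0.20 at 22 h and 0.16 at 144 h, PDC1 had -0.14 at 92 h and 0.20 at 187 h, and SUC2 had 0.13 at 22 h and -0.46 at 92 h.

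At 22 h the 75th percentile of gene signals over the spike-in probes was higher in mixed than in control fermentations by 0.54, with 1.76 and 1.88 on the mixed and 1.11 and 1.45 on the control arrays. The difference was not tested.

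The numbers of genes called were compared with splits of the arrays that mix the groups. For the average over times only the real split of 100, 1 of 100, gave as many genes, with 374 in an additive model and 1 as the highest other count. For the steps from 22 h to 92 h, 92 h to 144 h and 144 h to 187 h 1 of 35 splits gave as many, with 4081, 1013 and 700 genes and highest other counts of 12, 1 and 7. Each other split of a step put arrays of both times on both sides, so the time difference entered the spread. Each other split for the average likewise put arrays of both kinds on both sides, so the kind difference entered it. Low counts were thus built in, and none of these splits can measure how many calls chance gives. Split into slides or crossed between slide and kind, the arrays gave 0 and 0 genes, limma being the test, against 374. If same-numbered arrays of a kind shared a vessel, these are the only other splits that keep vessels whole. They are too few to exclude chance for the average.

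The higher PAU genes might have come from 1 pool of near-identical transcripts, from the place of the arrays on the slides or from mixed fermentations being further along. The spread of the 25 average differences was 1.01 times their median standard error (standard deviation 0.236). Variation shared by all PAU probes of an array enters that error but not the spread. The ratio therefore cannot show whether the members rose alike, and a single pool read by all probes stays open. Since mixed arrays lay in 1 row of both slides and controls in the other, place was tested on lists matched on signal. The highest median of 10000 such lists was 0.15 against 1.12, which sets aside a place effect that acts by signal but not one acting on these probes. The planned test of a lead at 22 h could not decide. PAU genes rose from 22 h to 92 h in the control fermentations (0.70 and 0.95 by slide, or 0.82 over both), as a lead requires. A test chosen later argued against a lead along the course sampled in the controls. The PAU rise was at least 0.95 of the same slide's control step to 92 h. The other genes had moved by only -0.015 and 0.13 of that step on the first principal component. A short lead with a passing PAU peak between 22 h and 92 h stays open, for lack of arrays between these times, and from 92 h the lowest of 6 mixed arrays stood 0.48 above the highest of the 8 control arrays.

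The lower ribosomal protein genes from 92 h might have come from mixed fermentations being further along, from scaling or from compression of bright signals. A lead in time stays open. Against it, oxidative phosphorylation genes, which rose from 92 h on, were lower in mixed fermentations, with slide values from -0.24 to -0.17 at 92 h and 144 h, but on the first principal component of the other genes the mixed arrays lay ahead by 0.14 and 0.62 of the next control step at 92 h and by 0.68 and 0.74 at 144 h. Relative to the all-gene median the list lay between -0.45 and -0.29 with quantile normalization, normexp and an added constant at 3 times. The lowest median of 10000 lists matched on signal at 144 h was -0.092, against -0.46.

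The genes called higher at 187 h might owe to a dark central area of the first control array. Spots there deviated from the mean of their probe by a median of -0.27 log2. On the first mixed array of 187 h the median was 0.18, against 0.03 to 0.06 on the other arrays. Both deviations would raise mixed minus control differences there, and their shares were not told apart. Of the genes called higher 45.4% had a spot in that area, against 18.8% of all tested and 3.64% of the genes called lower. Part of the calls therefore likely came from that area. With the area left out 14 of the 79 higher calls with a spot there remained and 93 of the 95 others, but of the lower calls with no spot there only 122 of 265 remained, and the cause of that was not tested. Identifiers absent from the annotation made up 28 of 174 higher and 5 of 275 lower calls (Fisher exact p = 2.16e-08). Low signal alone gave as many in 0.0059 of 10000 draws within signal deciles (19.2 expected). For the dark area the test was open, with 35.7% of these identifiers against 18.8%. Of the 28, 18 were still called higher with the area left out, 21 with a constant added to dim signals, 19 with quantile normalization and 13 with normexp.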

How the results depend on the processing

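Spike-in scaling changed the counts of genes. From 22 h to 92 h it gave 4716 (335 higher), with 2666 shared. The other counts moved by over 1.5 times, to 89 at 22 h, 6 at 92 h, 2 at 144 h, 42 at 187 h, 135 for the average, 1.1e+02 from 92 h to 144 h (43 higher and 64 lower), 51 from 144 h to 187 h and 18 for a difference varying with time. It also reversed IAH1 (-0.68) and MET4 (-0.59) from 22 h to 92 h, as the deposited table did (-0.33 and -0.25). The deposited table, whose medians differ by time, gave 3377 genes from 92 h to 144 h and 4751 from 144 h to 187 h. Quantile normalization gave 1 gene at 144 h. A replicate block, which is also the slide, gave 1 gene at 22 h and 1 for a difference varying with time. Leaving out probes with 2 differing spots gave 2 for the latter. With only the compared times fitted, 0 genes passed at 92 h and 0 at 187 h in limma, where 348 and 1790 had an unadjusted p under 0.05 in the full model, and 88 passed from 144 h to 187 h. Leaving out the dark area gave 269 at 187 h, 238 of them shared. For the average, a vessel block gave 216 genes, the mean of each vessel 0, and leaving out 92 h, 144 h and 187 h gave 307, 15 and 0. Of the 67 lists called for mixed against control and the 37 called for the steps, camera with an estimated correlation called 0 and 0, and fry called 0 of the former. For the steps fry called 49 lists, of which 33 were among the 37.

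With single arrays left out, counts ranged from 1 to 50 at 22 h, 0 to 1 at 92 h, 0 to 2 at 144 h, 2 to 576 at 187 h, 56 to 864 for the average, 3614 to 3884 from 22 h to 92 h, 251 to 869 from 92 h to 144 h, 85 to 682 from 144 h to 187 h and 0 to 33 for a difference varying with time. Lists ranged from 59 to 70 for mixed against control and from 37 to 41 for the steps. The average count fell most without the second control arrays of 92 h (56) and 144 h (99), the second mixed array of 144 h (142), the first control array of 187 h (172) and the first mixed array of 92 h (178). It was 220, 269 and 340 without the second mixed arrays of 92 h, 187 h and 22 h, 245 without the second control array of 22 h, 277 without the first control array of 92 h, 293 without the first mixed array of 22 h and 864 without the first mixed array of 187 h. At 22 h it was 30 and 1 without the first and second mixed and 50 and 3 without the first and second control array, at 144 h 2 and 1 without the first and second control array, and at 187 h 2 without the first control and 88 without the second mixed array. AGP1 at 92 h was lost (0 genes by limma) without the second mixed or either control array. From 92 h to 144 h the count was 626 without the first mixed and 286 without the first control array of 144 h, and 415 and 251 without the second mixed and control arrays of 92 h. From 144 h to 187 h it was 238 and 334 without the first and second mixed and 85 without the second control array of 144 h, and 251 without the first control and 427 without the second mixed array of 187 h. For a difference varying with time it was 9, 33 and 11 without the first control array of 22 h, the second control and the second mixed array of 187 h. Deviations of same-numbered arrays from their groups correlated between 0.03 and 0.31 over the 6 pairs of control groups and between -0.13 and 0.49 over the 6 pairs of mixed groups, so a shared vessel was neither shown nor excluded. Of the 6256 probes, 5970 to 6130 were well above background per array, and whether depth limited the others was not tested. Why single arrays weigh so much was not tested.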

Other observations

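From 22 h to 92 h haploid- and mating-type-specific genes rose, 19 of 29 with 3 falls, 20 and 3 adjusted over the list alone, and a median of 0.91 (adjusted p = 0.000822, or adjusted p = 0.459 with an estimated correlation). STE3 (at least 40.1-fold) and MF(ALPHA)1 (at least 10.9-fold) rose, and NEJ1 (-0.92) and FAR1 (-0.86) fell. Of 13 mitochondrially encoded genes 10 rose, with COX3 (2.15) and ATP8 (1.76) and 10 also adjusted over the list alone, with a median of 1.10 (adjusted p = 0.0148, or adjusted p = 0.616 with an estimated correlation). Both medians turned negative with spike-in scaling, and the haploid-specific median was 0.50 with quantile normalization and 0.41 with normexp.

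The neighbours AGP1, KCC4 and YCL023C on chromosome III were looked at after their values were seen. YCL023C was higher in mixed fermentations at each time, by 0.63, 2.13, 1.72 and 1.10, while AGP1 was higher mainly at 92 h (1.93) and KCC4 mainly at 187 h (1.60).

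The 75th percentile of gene signals over the spike-in probes was 1.28, 0.44, 0.05 and -0.15 at the 4 times in control and 1.82, 0.33, 0.14 and -0.19 in mixed fermentations. It fell from 22 h to 92 h, while the later steps lay within the spread of the duplicates (standard deviations up to 0.59). As a hypothesis, the share of messenger RNA in total RNA could have fallen as cells left growth, which spike-in scaling would show as the all-gene median of -1.09 from 22 h to 92 h. That median rests on the same spike-in signals, so it is no separate evidence, and the hypothesis was not tested.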
